A study of Homo sapiens with 16 samples.

How the data were processed

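RNA from human neuroblastoma cells was measured on 16 Affymetrix U133 Plus 2.0 arrays, 1 array per line or clone and time, after 4 ug of RNA was labelled for each. Per the labels, the signals came from MAS5 and GCOS, Affymetrix's own programs, whose versions were not given. The deposited values are probe set intensity on a linear scale, and each array was scaled by the authors with 1 factor, since the mean of the signals without the lowest and highest 2% was between 99.985 and 99.987 on every array. No probe set had been removed. Array signals carry no read depth, so the number of arrays and the signal over background limit the precision. The array median signal ran from 17.8 to 25.4, and the largest signal on an array from 8535 to 14289.

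The table held 54675 probe sets, of which 62 controls were left out of the gene tests. Of the rest, 41091 carried 1 gene symbol, 1801 several and 11721 none. Symbols of 41037 probe sets were updated through their Entrez gene identifiers. Probe sets with 1 symbol named 19775 genes, and each gene was read from the probe set with the highest mean log2 signal over the 16 arrays. A pseudocount of 3.689, the 20th percentile of all signals, was added before the log2 step, so changes are on that scale, which understates those of genes with low signals. A gene was kept in a fit where its signal reached the array median on at least 2 arrays of that fit.

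The MYCN comparisons used 6 arrays, the 0 h, 24 h and last arrays of SKNAS-NmycER and SHEP-21N, with the line as a block. The DKK1 comparisons used the 8 IMR32-DKK1 arrays with the clone as a block, and the difference between the clones came from the same fit. Differences between lines or clones in the response were tested as an interaction over all times after 0 h, where the 3 times of a line stand in for replicates and the 0 h arrays, 1 each, are taken to vary like them. Each fit was made with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3 (the data.table package at 1.17.8), two-sided, with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these samples. That the arrays of a clone belong together was checked on the deviations from each time's mean, which correlated within a clone with r between 0.2274 and 0.4726 over 6 pairs of times.

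The design held 22 gene lists with 710 genes, of which 641 were measured by a probe set with 1 symbol. Lists were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 and again with an estimated correlation, and with fry, which asks whether a list's own genes move 1 way. No camera call of any comparison held with an estimated correlation. List p-values were adjusted over the lists of a comparison, and members were counted over all genes and adjusted over the list alone. SKNAS-NmycER and SHEP-21N had 1 array per time, so their courses are given as values without a p-value. The median change of a list in a line was set against 10000 random lists of the same size matched on expression in 20 bins.

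Fry called 0 lists in every MYCN and DKK1 comparison and between the clones, and 2 in each difference of responses. Comparisons, lists, alternatives and the rule for named genes were set before the data were examined. The rule names 13 genes always: MYCN, MYC, DKK1, DKK2, DKK3, DKK4, KREMEN1, KREMEN2, LRP5, LRP6, AXIN2, SYNPO2 and ODC1. It adds, per comparison, the 10 higher and 10 lower genes with the largest change past the threshold that moved the same way in both lines or clones. Where fewer than 5 passed in a direction, it takes the 5 with the largest mean change among those that moved by at least 1 on the log2 scale in both. For the clone contrast and the interactions it takes the 5 largest changes past the threshold each way. For the courses of SKNAS-NmycER and SHEP-21N it takes 10 genes each way by the smaller change of the last 2 times, and for each list up to 4 members. Probe sets with several symbols or none were not named.

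The fits were tested on simulated data of the same design, in which genes varied independently of each other. Noise was drawn from variances that limma had already pulled toward the trend, which spread less than real ones. Simulated changes with time were the same in both lines or clones. The recovered shares can therefore overstate those in the data, and 0 calls do not show that changes of that size are absent. Of the simulated changes of 2 on the log2 scale, limma recovered 88.06% at 24 h and 83.58% at the late time of the MYCN fit. It recovered 88.06% at 24 h and 288 h of the DKK1 fit, 92.54% in the clone contrast, 67.16% in the interaction of clones and 55.22% in the interaction of lines. Camera called the 1 list that had been shifted and 0 others, but correlated genes were not simulated, so false list calls from them were not tested. For changes of 1, the recovered shares were 41.79% and 34.33% for MYCN, 68.66% and 67.16% for DKK1, and 8.955% for the interaction of lines. Unchanged genes made up 20 of 169 calls at 24 h and 10 of 154 at the late time of the MYCN fit, and 14 of 183 at 24 h and 10 of 176 at 288 h of the DKK1 fit. They made up 12 of 192 calls in the clone contrast, 8 of 136 in the interaction of clones and 11 of 107 in the interaction of lines, a share above the nominal 5% in each.

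The alternatives were a pseudocount of 1 or of 13.12 (the 40th percentile), quantile normalisation, median centring, no filter, a stricter filter, the mean of a gene's probe sets, every probe set on its own, no replicate block, eBayes without a trend, 1 fit over 16 arrays, all times after 0 h pooled, camera with an estimated correlation, and each array left out in turn. After the signals were seen, a block for a batch visible in the spike-in controls and another MYCN probe set were added. Overlap of the calls of the MYCN and DKK1 comparisons could not be tested, since both called 0 genes at the times set for it.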

Results

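The series asks how MYCN activity and the Wnt antagonist DKK1 change gene expression in neuroblastoma cells, and it holds 4 time courses with 1 array per time. SKNAS-NmycER cells carry a MYCN protein fused to an oestrogen receptor domain, which 50 nM 4-hydroxytamoxifen activates, and were sampled at 0, 24, 72 and 144 h. SHEP-21N cells carry a MYCN transgene held off by 50 ng/ml tetracycline, and were sampled at 0, 8, 24 and 120 h after its removal. IMR32-DKK1 cells, from a line with amplified MYCN, carry a DKK1 transgene switched on by 50 ng/ml doxycycline, and clones c63 and c66 were sampled at 0, 24, 72 and 288 h. No array followed a drug in cells without a transgene, so drug, time in culture and transgene move together. Signals are MAS5 intensities scaled to the same trimmed mean on all 16 arrays, and log2 changes below are of limma fits or of 1 array against its 0 h array. Arrays of the same line or clone correlated across probe sets with r between 0.9413 and 0.9797, clone c63 with clone c66 between 0.9426 and 0.9592, and other pairs between 0.6936 and 0.8565.

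The comparison named by the series title is DKK1 RNA after MYCN activation. DKK1, a secreted inhibitor of canonical Wnt signalling, had lower signals after 24 h in both MYCN lines on its only probe set. In SKNAS-NmycER the signal was 1268 at 0 h, 620 at 24 h, 344 at 72 h and 489 at 144 h. In SHEP-21N it was 812 at 0 h, 1020.0 at 8 h, 274 at 24 h and 494 at 120 h. The fitted log2 change was -1.29 at 24 h (SE 0.27, 95% confidence interval -1.92 to -0.67, lower in 2 of 2 lines) and -1.04 at the late times (interval -1.66 to -0.42). Neither passed the threshold over 12910 genes, with adjusted p of 0.3811 and 0.4018. DKK3, a related secreted protein, had log2 values of -1.12 and -1.48 (SE 0.24, adjusted p of 0.3811 and 0.3264), with signals from 625 to 298 in SKNAS-NmycER and from 1249 to 333 in SHEP-21N. MYC, the paralogue of MYCN, had log2 values of -1.54 and -1.36 (SE 0.53, adjusted p of 0.4259 and 0.4896). Its signal went from 236 to 44.8 in SKNAS-NmycER, and in SHEP-21N from 651 through 163 at 24 h back to 484 at 120 h. ODC1, the polyamine enzyme and a known MYC target, had values of 0.85 and 0.64 (SE 0.18, adjusted p of 0.3811 and 0.4081), and its SKNAS-NmycER signal went from 1802 to 3382. KREMEN1, a DKK1 receptor with signals of 5.89 to 30.68, had values of -0.70 and -0.18, with opposite directions in the 2 lines at both times (-1.53 and 0.14, then -0.66 and 0.30, SKNAS-NmycER first). The Wnt co-receptors had 0.15 and -0.38 for LRP5 (0.03 and -0.79 by line at the late times) and 0.16 and 0.33 for LRP6. Without the SKNAS-NmycER 0 h array DKK3 passed at 24 h (-1.40, 0.04923) and late (-1.76, 0.04606). SYNPO2, an actin-binding protein, had -0.40 and -0.73, and DKK2 and DKK4 were near the floor of the arrays.

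MYCN RNA was read differently by its probe sets. The MYCN probe set with signal in SHEP-21N had 14.8, 509, 272 and 630 over that course, while the MYCN probe set with the highest mean over all arrays stayed at 1.61 or lower there. In IMR32-DKK1 the latter lay between 4497 and 5608. In SKNAS-NmycER the former stayed at 8.19 or lower, in cells where the switch acts on the MYCN protein.

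**Figure D1:**
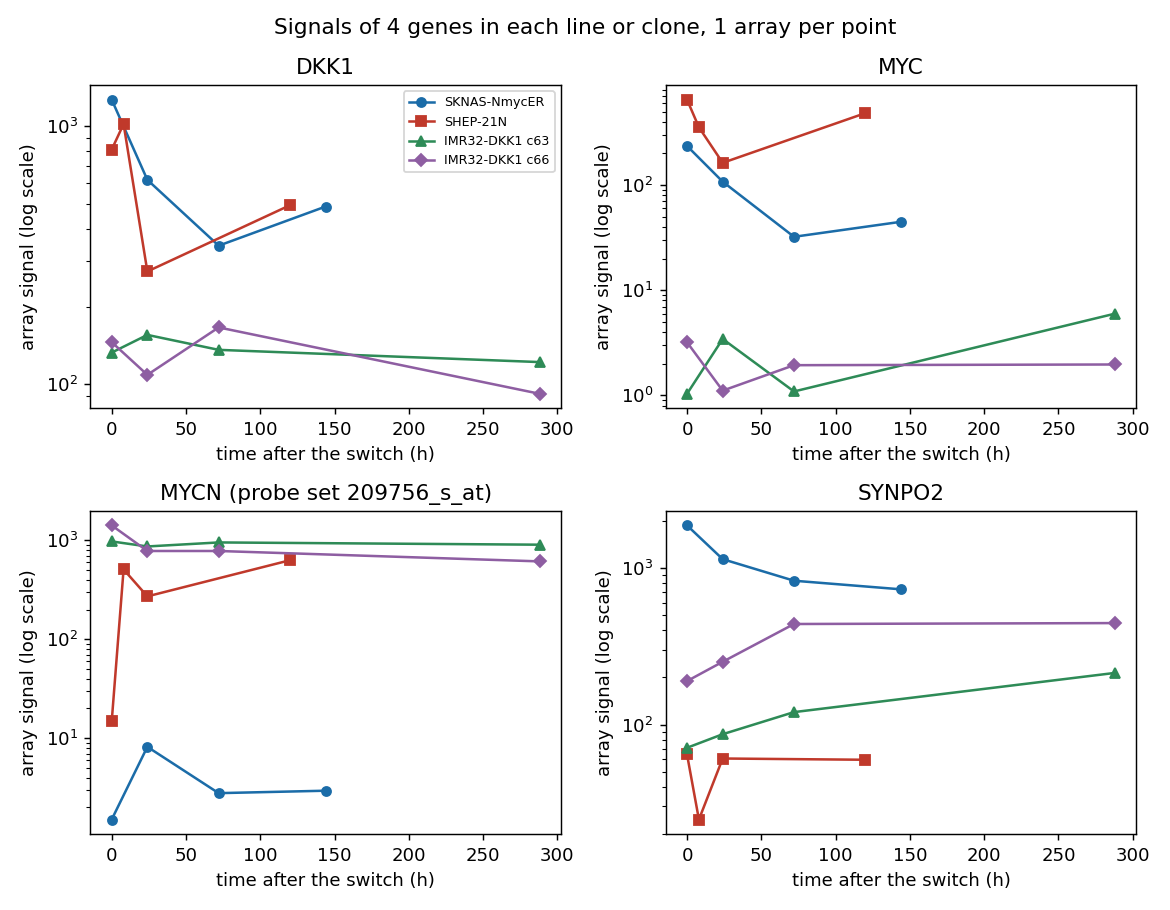
Array signal on a log axis against hours after the switch for DKK1, MYC, MYCN and SYNPO2, with 1 point per array and 1 line per cell line or clone. DKK1 went from 1268 to 489 in SKNAS-NmycER and from 812 to 494 in SHEP-21N, and SYNPO2 from 71.0 to 214 in clone c63 and from 189 to 444 in clone c66.

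At 24 h of MYCN activity, growth and cell cycle genes lay higher in the fit over both lines. All 40 mitosis genes and 39 of 40 DNA replication genes had positive fitted values (medians 0.76 and 0.94), mostly from SHEP-21N. In SKNAS-NmycER the medians were -0.03 for mitosis, with 21 of 40 lower, and 0.06 for DNA replication. The replication factor MCM10 changed by 3.11 in SHEP-21N and by 0.10 in SKNAS-NmycER, and the kinetochore gene SPC25 by 3.24 and -0.32. Of the ribosome biogenesis genes, which make and assemble ribosomal RNA, 39 of 41 were higher (median 0.32), and POLR1A, the largest RNA polymerase I subunit, had 0.97. Nucleotide and polyamine synthesis genes were higher for 25 of 26 (median 0.54), with RRM2 at 1.46, TYMS at 1.15 and CTPS1 at 0.93. Chaperones and degradation factors of the unfolded protein response were lower (median -0.51), with DNAJB9 at -1.42, HERPUD1 at -1.33 and XBP1 at -1.01.

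By camera, 7 lists moved up and 7 down at 24 h, and by fry 0 were called. DNA replication (adjusted p = 5.19e-18), mitosis (6.90e-17), nucleotide and polyamine synthesis (2.91e-12), ribosome biogenesis (4.23e-09) and cholesterol synthesis (median 0.26, 0.01343) moved up, each with adjusted p = 0.4631 with an estimated correlation. Cholesterol genes had 0.34 in SKNAS-NmycER and 0.03 in SHEP-21N, with 9 of 16 higher there, and ribosome biogenesis 0.51 and 0.15. Translation factors and tRNA synthetases moved up in the fit (median 0.13, 0.01219, and adjusted p = 0.6126 with an estimated correlation), but their median was 0.28 in SKNAS-NmycER and -0.11 in SHEP-21N. Cytosolic ribosomal proteins had a median of 0.15 (0.0005838, and adjusted p = 0.6438 with an estimated correlation), which turned to -0.04 under quantile normalisation, and was 0.34 in SKNAS-NmycER and -0.06 in SHEP-21N. The unfolded protein response (2.17e-08), extracellular matrix and integrins (median -0.26, 0.0009277), p53 targets and CDK inhibitors (-0.33, 0.003569), and actin cytoskeleton and SRF targets (-0.40, 0.004261) moved down. The ATF4 stress response moved down in the fit (-0.37, 0.004261), but its median was 0.20 in SKNAS-NmycER and -0.83 in SHEP-21N, so the fitted change comes from SHEP-21N. Lower too were the interferon response (-0.26, 0.01219) and immediate early genes (-0.30, 0.01219), and each of these 7 had adjusted p = 0.4631 with an estimated correlation. Matrix genes had -0.55 in SKNAS-NmycER and -0.09 in SHEP-21N, with 22 of 37 lower there, and the unfolded protein response -0.18 and -0.83. Wnt beta-catenin targets (-0.26, adjusted p = 0.1916), Wnt ligands and receptors (-0.01, 0.4178), glycolysis and hypoxia (0.09, 0.1883), adrenergic (-0.06, 0.853), mesenchymal (-0.15, 0.06514), oestrogen receptor targets (-0.10, 0.853) and immune markers (0.03, 0.853) were not called. Schwann markers had a median of 0.09 and a mean of -0.06 (0.8684).

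No single gene passed limma's threshold at 24 h, with 0 of 12910 called, 1299 at an unadjusted p under 0.05 and a smallest adjusted p of 0.2014. In the lists that camera called, 13 nucleotide synthesis genes, 6 unfolded protein response genes and 1 immediate early gene passed when adjusted over the list alone, against 0 over all genes. The largest changes shared by both lines, not past the threshold, were DEFB124 at 2.54, C10orf95 at 2.33, HTR6 at 2.30, LOC101927131 at 2.27 and TTR at 2.22, and CCDC106 at -2.44, CLIC3 at -2.42, B3GALT2 at -2.37, DCHS1 at -2.28 and PSG7 at -2.13. PSG7 lay under the array median on most SKNAS-NmycER arrays, so its change there is one of low signals. In SHEP-21N its signal was 687 at 0 h and 102 at 24 h (-2.71). Across genes the lines' changes correlated with r = 0.0891 (rho = 0.1149; genes are not independent replicates). At least 2-fold changes were shared by 54 genes upward and 82 downward, against 26.95 and 33.56 if the lines were independent, and went opposite ways for 51 (higher in SKNAS-NmycER) and 38, against 28.98 and 31.21. Without the SKNAS-NmycER 0 h array 161 genes were called, PSG7 among them (0.02926), and 6 lists remained, as ribosomal proteins, translation factors, p53 targets, matrix, actin, interferon, cholesterol and immediate early genes lost their calls (adjusted p between 0.05729 and 0.855). Without its 24 h array 8 lists remained, as ribosome biogenesis (0.06468), matrix (0.2841), interferon (0.1044) and cholesterol genes (0.2841) lost theirs, and ribosomal proteins (-0.05) and translation factors (-0.07) changed sign. Without the SHEP-21N 0 h array mitosis (0.06, adjusted p = 0.4147), interferon (0.0727) and ATF4 genes (0.6427) were not called, and without its 24 h array p53 targets (0.09301), ATF4 (0.9278) and immediate early genes (0.3881) were not.

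At the late times, 144 h in SKNAS-NmycER and 120 h in SHEP-21N, ribosome biogenesis genes were higher for 41 of 41 (median 0.43), with POLR1C, a polymerase subunit, at 0.83 and the methyltransferase FBL at 0.76. Matrix genes were lower for 35 of 37 (median -0.43), with COL5A1 at -1.29 and the collagen cross-linking enzyme LOXL2 at -1.12. Markers of adrenergic neuroblasts had a fitted median of -0.40, which comes from SKNAS-NmycER: its median was -0.55, while SHEP-21N had -0.10 with 7 of 14 lower. Among them were the receptor kinase RET at -2.25, SCG2, a granule protein, at -1.56 and CHGA at -1.45. RET was low in SHEP-21N, with signals of 26.9 at 0 h and 3.32 at 120 h. Mesenchymal markers had a fitted median of -0.24, with -0.36 in SKNAS-NmycER and -0.05 in SHEP-21N, where 15 were lower and 14 higher, and FN1, which encodes fibronectin, had -1.63.

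By camera 6 lists moved up and 5 down, and by fry 0 were called. Ribosome biogenesis (adjusted p = 1.11e-14, and adjusted p = 0.4717 with an estimated correlation), nucleotide synthesis (median 0.42, 1.84e-09, and 0.3962 as adjusted p with an estimated correlation), mitosis (0.55, 1.01e-11) and DNA replication (0.65, 3.05e-11) moved up. The last pair, whose medians were -0.04 and -0.04 in SKNAS-NmycER and 1.16 and 1.46 in SHEP-21N, had adjusted p = 0.5276 with an estimated correlation, as had translation factors (0.21, 8.37e-05). Ribosomal proteins moved up (median 0.15, 6.69e-05, and adjusted p = 0.6391 with an estimated correlation), but had -0.01 under quantile normalisation. Matrix genes (7.08e-11), adrenergic markers (8.98e-05) and actin genes (-0.35, 0.002863) moved down, each with adjusted p = 0.3962 with an estimated correlation. Mesenchymal markers (0.002518, and adjusted p = 0.4717 with an estimated correlation) and the unfolded protein response (-0.52, 6.15e-08, and adjusted p = 0.5276 with an estimated correlation; -0.14 in SKNAS-NmycER and -0.71 in SHEP-21N) moved down too. In the lists that camera called, 9 matrix, 5 adrenergic, 2 mesenchymal, 2 unfolded protein response and 1 ribosome biogenesis gene passed when adjusted over the list alone, against 0 over all genes. The other lists were not called, among them p53 targets (-0.04, 0.6937) and Wnt targets (-0.14, 0.3294). ATF4 genes (median -0.004464, 0.8594) were read upward by camera, and oestrogen receptor targets had a median of 0.10 and a mean of -0.14.

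Of single genes, limma called 0 of 12910 at the late times, with 1290 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0907, for SCG2. The largest shared changes, not past the threshold, were HTR6 at 2.95, LINC00919 at 2.47, GAL3ST2 at 2.41 and TEX15 at 2.38, and OGDHL at -2.53, PSG7 at -2.30, RET at -2.25 and CLIP3 at -2.19. PSG7, of low signal in SKNAS-NmycER, changed by -3.33 in SHEP-21N. At least 2-fold changes were shared by 56 genes upward and 104 downward, against 22.5 and 37.32 if independent (r = 0.1193 across genes). They went opposite ways for 61 (higher in SKNAS-NmycER) and 47, against 31.48 and 26.68. Without the SKNAS-NmycER 0 h array 58 genes were called, PSG7 among them (0.04519), and 7 lists, with adrenergic (0.09825), mesenchymal (0.2949), actin (0.05382), translation (0.2949) and ribosomal protein genes (0.3912) no longer among them. Without the SHEP-21N 0 h array 19 genes were called, TEX15 among them (0.03592), and the medians of DNA replication and mitosis turned to -0.12 and -0.15, with no call for the unfolded protein response (0.09912). Without the SKNAS-NmycER 144 h array 1 gene was called and actin genes were not (0.1177), and without the SHEP-21N 120 h array ribosomal proteins were not (0.2312).

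The SKNAS-NmycER course asks what MYCN does over 144 h in 1 line, with 1 array per time and so no p-value. Genes of ribosome assembly and nucleotide synthesis had higher signals from 24 h on: WDR74 had 300.7, 723, 667 and 610, RRP1B 1208, 2271, 2454 and 2323, and IMPDH1, which makes guanine nucleotides, 124, 330, 381 and 296. The ribosome biogenesis median was 0.51, 0.47 and 0.42 at 24, 72 and 144 h, above the medians of all 10000 random lists. Matrix genes were lower (-0.55, -0.53 and -0.56, below all random lists). Mesenchymal markers were lower too (-0.39, -0.40 and -0.36), with FN1 at 198 and then 36.6 and the surface protein THY1 at 850 and 264. Adrenergic markers were lower (-0.40, -0.80 and -0.55), with the peptide NPY at 627 and 200.3. ATF4 genes were higher (0.20, 0.46 and 0.40), with CTH, which makes cysteine, at 98.7 and 315 and ASNS at 445 and 990.4. Cell cycle lists stayed near 0, with medians of 0.06, 0.03 and -0.04 for DNA replication and -0.03, -0.03 and -0.04 for mitosis. Wnt beta-catenin targets had -0.35, -0.33 and -0.19, and oestrogen receptor targets, which 4-hydroxytamoxifen can touch directly, 0.003, 0.15 and -0.04. Ribosomal proteins had 0.34, 0.19 and 0.18, which became -0.02, -0.02 and 0.00 under quantile normalisation. Controls moved with this course as well: the actin 3' over 5' ratio was 1.67 at 0 h and 1.92 to 1.95 after, that of GAPDH 1.04 and 1.13 to 1.16, BioB 103 and 145 to 148, and 28S ribosomal RNA 859 at 0 h and 2067 at 144 h. The state of the RNA or array and MYCN activity were thus not varied apart between 0 h and the later times.

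Of 11958 genes kept in SKNAS-NmycER, 375 were at least 2-fold higher and 468 lower at 144 h. Among the largest were JAG2, a Notch ligand, with signals of 13.8, 134.5, 257 and 255, HES6 with 8.22 and 203, and STEAP1 with 54.0 and 571 (9.95-fold). NPW, a neuropeptide, had 0.603 at 0 h, under the pseudocount, and 296.2 at 144 h. On the lower side were CCK, a peptide hormone, with 171 and 13.6, MYC (4.94-fold lower), ITGB8 with 147 and 27.9 (4.75-fold) and the calcium pump ATP2B4 with 838 and 186 (4.44-fold). The others named by the rule were SOX7, HTR6, SLC19A3, INHBE, TEX15 and RTN4RL1 upward and SLC22A17, SLC35F3, GPBAR1, RAP1GAP2, PTCHD1 and PAPSS2 downward.

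The SHEP-21N course asks the same over 120 h after the transgene was released. DNA replication genes were 3.62-fold higher in the median at 8 h already, with log2 medians of 1.86, 1.85 and 1.46 at 8, 24 and 120 h, and 34, 36 and 29 of 40 at least 2-fold higher. Mitosis genes had 1.21, 1.46 and 1.16, and both lists lay above all 10000 random lists at each time. MCM10 had signals of 33.5, 364, 318 and 189, ORC1 18.7, 125, 116 and 136, RRM2, the ribonucleotide reductase subunit, 293, 1850, 1893 and 1251, and CCNB1, the mitotic cyclin, 499.5, 1357, 1694 and 1454. Stress genes were lower: the unfolded protein response list had -0.54, -0.83 and -0.71, with HERPUD1 at 2740, 964, 644 and 1070. ATF4 genes had -1.43, -0.83 and -0.24, with DDIT3, the stress factor CHOP, at 1858, 74.3, 142 and 852. Immediate early genes had -0.78, -0.33 and -0.07, with EGR1 at 185, 9.38, 313 and 447. Nucleotide synthesis had 0.50, 0.40 and 0.49, ribosome biogenesis 0.38, 0.15 and 0.41, and p53 targets -0.52, -0.28 and 0.20. Ribosomal proteins had -0.12, -0.06 and 0.13, the last of which became -0.01 under quantile normalisation.

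Of 11926 genes kept in SHEP-21N, 436 were at least 2-fold higher and 661 lower at 120 h, after 702 and 1040 at 8 h. E2F1, an S-phase transcription factor, had 7.81, 154, 89.8 and 68.6, ATAD2, a chromatin ATPase, 51.5, 476, 388 and 333 (6.10-fold at 120 h), and HAUS8, a spindle protein, 1.33 and 51.3, from under the pseudocount. HUWE1, a ubiquitin ligase, had 1033 and 9917 on the probe set used, but another HUWE1 probe set had 456, 382, 557 and 588, so the probe sets disagree. On the lower side were the pregnancy-specific glycoproteins PSG7 (687 and 64.8), PSG4 (1304 and 207) and PSG9 (329 and 78.9), SELENOP, a selenium carrier, with 652 and 154, and the heat shock gene HSPA6 with 68.7 and 6.45. The others named by the rule were PXN-AS1, ANHX, C2orf81, TMIE, PRSS53 and CD300C upward and IL11, CASKIN2, TMEM229B, SYNGR3 and GCNT2 downward.

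**Figure D2:**
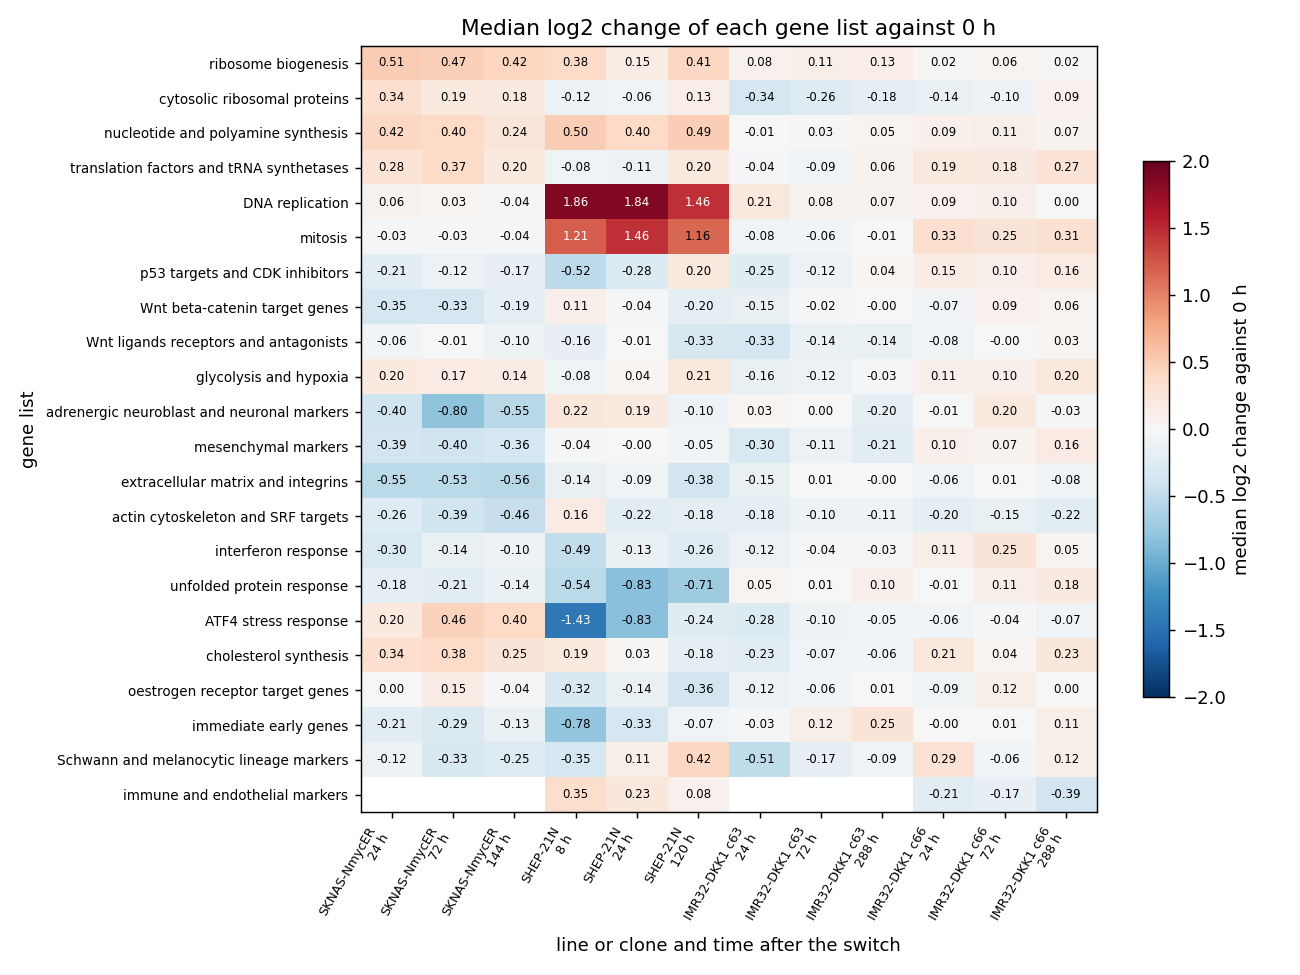
Median log2 change against 0 h of 22 gene lists (vertical) in each line or clone and time (horizontal), 1 array per column, with blank cells where fewer than 3 members were kept. DNA replication reached 1.86 in SHEP-21N and 0.06 in SKNAS-NmycER, and ribosomal proteins, whose direction flips under quantile normalisation in several columns, ranged from -0.34 to 0.34.

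Whether the lines differ in their MYCN response was tested over all times after 0 h, SKNAS-NmycER minus SHEP-21N. Cell cycle genes had the higher change in SHEP-21N: E2F1 changed by 3.15 there and by -0.85 in SKNAS-NmycER (difference -3.997, adjusted p = 0.02905), and MYBL2, a regulator of mitotic genes, by 2.74 and -0.76 (-3.50, 0.03857). The helicase subunits MCM2 (-2.03) and MCM5 (-2.53) and ORC1 (-2.64) differed with adjusted p = 0.0256 each. In the other direction NPW (5.25, 0.0459) and JAG2 (5.21, 0.0256) had the higher change in SKNAS-NmycER. CCN3, a matricellular protein (3.50, 0.04147), PER3, a clock gene (3.23, 0.0292), and BHLHE41 (2.86, 0.0425) had positive changes in SKNAS-NmycER and negative ones in SHEP-21N.

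Limma called 96 of 13296 genes, 26 with the higher change in SKNAS-NmycER and 70 with the lower, but 0 with eBayes without a trend, 27 without a filter, 63 with the mean of probe sets and 51 with every probe set. The genes named here all lost their calls without the trend. The spread in this test comes from the arrays after 0 h, so a deviation of either 0 h array, 1 per line, enters every difference. HAUS8 (-3.80, 0.0256), ATAD2 (-3.06, 0.01044) and HUWE1 (-3.04, 0.0008087, on the probe set that disagrees with the other) were among them. DNA replication differed by a median of -1.46 (camera adjusted p = 7.98e-35) with 17 members called over all genes and 33 adjusted over the list alone, and mitosis by -1.30 (1.53e-38) with 12 and 39, both called by fry (0.03421) and both with adjusted p = 0.1941 with an estimated correlation. ATF4 genes (0.90, 3.77e-06, and adjusted p = 0.6132 with an estimated correlation) and the unfolded protein response (0.38, 1.83e-05, and adjusted p = 0.4129 with an estimated correlation) differed upward, as did translation factors (0.40, 0.001423) and ribosomal proteins (0.26, 1.83e-05; 0.03 and not called under quantile normalisation), both with adjusted p = 0.721 with an estimated correlation. Mesenchymal markers differed by -0.33 (0.02691, and adjusted p = 0.5671 with an estimated correlation), and lost the call without the SHEP-21N 8 h array (0.05945), with the mean of probe sets (-0.15, 0.08927) and with eBayes without a trend (0.07914). DKK1 differed by -0.77 (SE 0.78, adjusted p = 0.747). The count was 1 without any of the SKNAS-NmycER 24, 72 or 144 h arrays or the SHEP-21N 24 h array, and 567 without the SHEP-21N 120 h array. NPW lost its call with 5 of the 6 arrays that could be left out, HUWE1 with 0, and the other 8 of the 10 genes with the largest differences with 4 each.

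Doxycycline was given to switch on DKK1 in IMR32-DKK1 cells, which have amplified MYCN. The DKK1 probe set stayed between 91.9 and 166 in both clones, with fitted log2 values of -0.09, 0.11 and -0.38 at 24, 72 and 288 h (SE 0.23, adjusted p of 0.9365, 0.9015 and 0.5913), so the arrays show no rise of DKK1 RNA on it. SYNPO2, an actin-binding protein, had higher signals at each later time in both clones: 71.0, 86.7, 120.0 and 214 in c63 and 189, 252, 438 and 444 in c66. Its log2 values were 0.34, 0.96 and 1.38 (SE 0.20), not past the threshold (adjusted p of 0.6693, 0.5451 and 0.494). Of the other SYNPO2 probe sets, 3 went the same way in both clones and 2 with low signals did not. Another went from 77.3 to 165 in c63 and from 197 to 366 in c66, but stayed at 197 at 24 h in c66. Without the c63 0 h array SYNPO2 had 1.01 at 72 h and 1.42 at 288 h, values that rest mainly on c66. In that fit LRP5 had -1.58, -1.59 and -1.37 at 24, 72 and 288 h, and MYCN -0.33 at 24 h. At 72 and 288 h KREMEN1 had -0.61 and -0.81, LRP6 0.68 and 0.75, and ODC1 0.31 and 0.31. The 0 h arm of that fit is the c66 0 h array alone, and the later c66 arrays are a batch of their own in the spike-in controls. Time and batch therefore coincide in it. The Wnt co-receptor LRP5 had -1.07, -1.08 and -0.86 (SE 0.29; adjusted p of 0.5655, 0.5451 and 0.5632). AXIN2, a feedback target of Wnt signalling, had -0.05, -0.06 and 0.21, and MYCN -0.25, -0.10 and -0.08, each on the probe set used. Another AXIN2 probe set went from 47.2 at 0 h to 22.5 at 288 h in c63 and from 39.9 to 12.6 in c66. A further AXIN2 probe set went from 72.6 to 77.0 and from 32.1 to 44.6, so the AXIN2 probe sets disagree. The MYCN probe set with signal in SHEP-21N went from 1419 to 614 in c66 and from 976.5 to 905 in c63. The other genes of the fixed set had values of -0.47, 0.14 and 0.06 for DKK3, -0.10, -0.32 and -0.52 for KREMEN1, -0.51, -0.62 and -0.64 for KREMEN2, 0.04, 0.20 and 0.28 for LRP6, and 0.17, 0.19 and 0.19 for ODC1. Every KREMEN1 probe set was lower in c66 at each time, and some far more than the one used. One of them went from 574 at 0 h to 68.3 at 288 h in c66 and from 239 to 304 in c63. On the probe sets used, the clones had opposite directions for KREMEN2 and LRP6 at all 3 times and DKK3 at 72 and 288 h. Directions were also opposite for DKK1 and KREMEN1 at 24 h, AXIN2 at 72 h and MYCN at 288 h. The 3 times share the 0 h arrays, so their values are not independent.

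Of the lists, ribosomal protein genes were lower for 41 of 41 at 24 and 72 h (medians -0.23 and -0.20) and 31 of 41 at 288 h (-0.05), but the medians were 0.003, 0.004 and 0.03 under quantile normalisation, and at 288 h -0.18 in c63 and 0.09 in c66. Camera called them at each time (adjusted p of 2.39e-23, 5.04e-17 and 0.007126; with an estimated correlation, adjusted p = 0.4431, 0.5782 and 0.722), and 12, 4 and 0 members passed adjusted over the list alone against 0 over all genes. RPL30 had -0.42 and RPS18 -0.47 at 24 h. DNA replication had 0.15 at 24 h (0.0001544, and adjusted p = 0.4239 with an estimated correlation) and 0.10 at 72 h (0.02966, and adjusted p = 0.5782 with an estimated correlation), with FEN1, a flap nuclease, at 0.49 at 24 h (0.84 in c63 and 0.14 in c66). By clone the medians of DNA replication were 0.21 and 0.08 in c63, above 100% and 96.5% of random lists, and 0.09 and 0.10 in c66, above 25.38% and 25.66%. Mitosis had 0.14 (0.0006825, and adjusted p = 0.6787 with an estimated correlation) and 0.13 (0.02966, and adjusted p = 0.8228 with an estimated correlation), which comes from c66: its medians were 0.33 and 0.25, with 37 and 36 of 40 higher, while c63 had -0.08 and -0.06, with 27 of 40 lower at both times. Wnt ligands and receptors (-0.10) and actin genes (-0.20) were called lower at 24 h (0.03226 each, and adjusted p = 0.4239 with an estimated correlation), the former with -0.33 in c63 and -0.08 in c66, and by fry 0 lists were called at any time. Wnt beta-catenin targets were not called, with medians of -0.05, 0.03 and 0.01 (adjusted p of 0.3952, 0.8715 and 0.8058; the means at the last pair of times were -0.09 and -0.03).

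Limma called 0 of 12704 genes at 24, 72 and 288 h, with 1001, 1128 and 1111 at an unadjusted p under 0.05, and 0 for any time with 590. The largest shared changes had signals of 79.3 or lower, among them LOC100422781 at 2.25 and FOXD2-AS1 at -2.56 at 24 h, FFAR1 at 2.00 and UCN3 at -2.57 at 72 h, and SULT2B1 at 2.05 and RHOV at -2.49 at 288 h. In spike-in controls added to each array, the 3 c66 arrays after 0 h stood apart from the other 5: Dap signals were 218 to 249 against 582 to 849, and BioB 168 to 195 against 57.4 to 74.5. A fit without the c63 0 h array has the c66 0 h array alone as its 0 h arm, so time and this batch coincide in it. With this batch as a block, the c66 0 h array no longer bears on the time terms, so the 0 h arm is the c63 0 h array alone. That fit called 33, 25 and 1 genes at 24, 72 and 288 h and 2 over any time, with mitosis medians of -0.04 and -0.08 and no call for actin genes (0.548). Without the c63 0 h array the counts were 1088, 1097 and 1746, and 597 for any time, and without the c66 0 h array 43 at 24 h and 26 at 72 h, with mitosis again at -0.04 and -0.08. Leaving out the 0 h or 24 h array of c63 ended the 24 h calls of DNA replication (0.3017 and 0.3572), Wnt ligands (0.482 and 0.5224) and actin genes (0.07608 and 0.1299). Leaving out the c66 24 h array ended those of mitosis (0.4217) and actin genes (0.07167), and the c66 0 h array that of actin genes (0.5631). At 72 h DNA replication lost its call without the c63 0 h array (0.8042) or the c66 72 h array (0.3374), and mitosis without the latter (0.3451). At 288 h ribosomal proteins lost theirs without the c63 0 h array (0.07, adjusted p = 0.7265) or the c63 288 h array (0.7364). Lists called at 288 h numbered 3 without any of the c63 24 h or the c66 0, 24 or 288 h arrays.

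**Figure D3:**
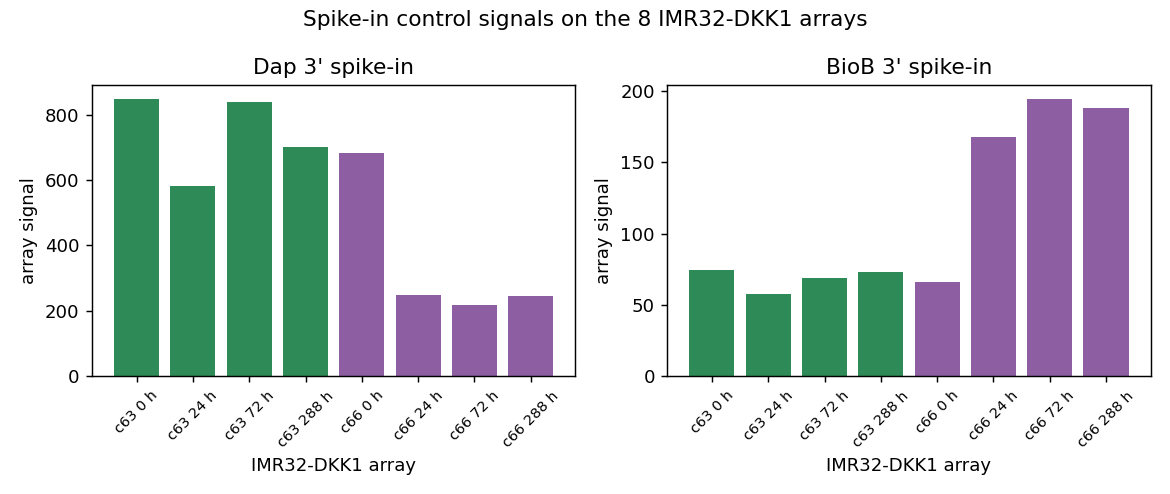
Signals of the Dap and BioB spike-in controls (vertical) on the 8 IMR32-DKK1 arrays (horizontal), with 1 bar per array. The 3 c66 arrays after 0 h had Dap signals of 218 to 249, against 582 to 849 on the other 5.

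The same arrays show how far the clones differ from each other. The times of a clone stand in for replicates in this contrast, so its p-values describe these clones and not others. Across all times c66 had more TMPRSS15, a serine protease (4.90, SE 0.18, adjusted p = 2.50e-06), AVPR1A, a vasopressin receptor (4.29, 2.56e-05), and SLITRK6, a neurite growth membrane protein (4.24, 4.53e-05), than c63. It had less NPY, a sympathetic neuropeptide (-4.03, SE 0.35, 0.0002013), the CDK inhibitor gene CDKN2A (-3.32, 3.22e-06; signals of 461 in c63 and 32.8 in c66 at 0 h), and LGALS1, a galectin (-3.27, 0.0006043). Of the neuroblast markers DCX (-1.50, 0.005779) and SNAP25 (-1.16, 0.00398) were lower in c66. Mesenchymal markers went both ways, with CDH11 (1.39, 0.001468) and SNAI2 (1.33, 0.01333) higher in c66 and LGALS1, also on that list, lower. SYNPO2 was higher in c66 by 1.44 (SE 0.14, 0.0004023). DKK1 (-0.12, 0.6716) and AXIN2 (-0.39, 0.05957) were not past the threshold.

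Limma called 1641 of 12704 genes between the clones, 703 higher and 938 lower in c66, and also NWD2 (3.39, 2.62e-05), ABCC8 (3.44, 0.002517), TNNT1 (-3.55, 0.0003399) and ACTL6B (-3.27, 0.0002974). No list was called by camera, the nearest being the unfolded protein response (-0.13, adjusted p = 0.05075), while 13 adrenergic, 10 Wnt ligand or receptor, 8 mesenchymal, 8 ribosome biogenesis and 8 matrix genes passed over all genes and 16, 11, 11, 10 and 9 adjusted over the list alone. The 3 later c66 arrays form their own spike-in batch, and a block for it leaves the c66 0 h array against the c63 0 h array, 1 array each, so clone and batch were not tested apart over all times. Between these 0 h arrays, which lie in 1 batch, the 5 largest upward genes had gaps of 1.93 (ABCC8) to 5.18 (AVPR1A). The 5 largest downward genes had -4.78 (LGALS1) to -2.63 (ACTL6B). Their differences were thus also seen within 1 batch, on 1 array each. The count was 513 with eBayes without a trend, where ABCC8 lost its call, 1045 with the mean of probe sets and 2536 with every probe set. KREMEN2 had -1.47 (0.03877) and DKK3 -0.72 (0.01967), calls that were lost with 6 and 4 of the 8 arrays left out in turn. Between the 0 h arrays KREMEN2 had -0.29 and DKK3 -1.13. The difference of KREMEN2 thus lies mainly on the later arrays, where clone and batch coincide. The count was 2937 without the c63 0 h array and 2969 without the c66 0 h array, and in these fits AXIN2 (0.03543 and 0.03407), KREMEN1 (0.01074 and 0.01101), LRP5 (0.02962 and 0.03324) and LRP6 (0.001093 and 0.001033) were called too. It was 679, 444 and 825 without the c63 24, 72 and 288 h arrays, and 649, 438 and 829 without those of c66. Camera called 2, 2 and 1 lists without the c63 0, 72 and 288 h arrays, and 2, 2 and 4 without those of c66.

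Whether the clones respond differently to doxycycline was tested over all times after 0 h, c66 minus c63. ACKR3, a chemokine receptor, changed by 3.37 in c66 (SD 0.18 over 3 times) and by -1.05 in c63 (SD 0.34), a difference of 4.42 (adjusted p = 0.001387), with 0.98 at 0 h in c66 and 91.6 in c63. The 0.98 lies under the pseudocount, so the size is not fixed: it was between 2.948 and 5.622 over the alternatives. LIMK1, a kinase of actin turnover, changed by -0.43 and 2.92 (-3.35, 0.01224), and the protease DPP9 by -1.19 and 2.99 (-4.18, 0.0004689). Both rises in c63 start from low signals on its 0 h array, 2.55 for LIMK1, under the pseudocount, and 4.04 for DPP9. Mitosis genes differed by a median of 0.38, with the cyclin-dependent kinase subunit CKS2 at 1.35 (0.001975) and the motor CENPE at 1.15 (0.01443). LRP6 differed by 0.96 (SE 0.24, 0.04647) on its main probe set, but the signal of another LRP6 probe set went from 105 to 65.9 in c66, so the probe sets disagree. SYNPO2 differed by 0.09 (0.9477). MYCN differed by -0.16, and by -0.87 with a pseudocount of 1, where the rule read another probe set.

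Limma called 492 of 12704 genes, 280 with the higher change in c66 and 212 with the lower, but 1, DPP9 (0.044), with eBayes without a trend, 132 with the mean of probe sets, 165 without a filter and 823 with every probe set. The others with the largest differences were KRT18 (3.77, 0.04567), SNAP91 (3.33, 0.03349), HBQ1 (3.09, 0.01469) and MAP4K1 (3.07, 0.04583) upward, and NTN3 (-4.55, 0.04485), RAB42 (-3.43, 0.03854) and FAM20C (-3.39, 0.01772) downward. Camera called mitosis (1.87e-06), with 6 members over all genes and 17 adjusted over the list alone, and ribosomal proteins (0.20, 0.001471; 0.08 and not called under quantile normalisation, 0.1529 without the trend), both with adjusted p = 0.8247 with an estimated correlation, and fry called mitosis and nucleotide synthesis (0.04063 each). The later c66 arrays are the spike-in batch, so this difference and the batch coincide in the design. The spread comes from the arrays after 0 h, so a deviation of the c66 or c63 0 h array alone also enters as a difference in response. The count was 249 and 200 without the c63 24 and 72 h arrays, 181 without the c66 24 h array and 846 without the c66 72 h array, and 322 without the c63 288 h array. Of the 6 arrays that could be left out, KRT18 lost its call with 6, SNAP91 with 5, LRP6 with 5, NTN3 with 4, RAB42 with 3 and FAM20C with 1, and MAP4K1 with 4 of 5. ACKR3, HBQ1, DPP9 and LIMK1 kept theirs with each, but the 0 h arrays could not be left out. Of the 8 alternatives, the mean of probe sets ended the call of DPP9 (-1.68, 0.05898).

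How the clones' changes compare was also read gene by gene: they correlated across genes with r = -0.03428, 0.05301 and -0.01712 at 24, 72 and 288 h. At least 2-fold changes were shared by 25, 23 and 24 genes upward, against 6.919, 6.173 and 9.469 if independent, and by 48, 64 and 57 downward, against 17.17, 18.53 and 19.23. Opposite changes were also more than if independent, with 49, 46 and 34 genes higher in c63 and lower in c66 (11.88, 11.47 and 13.69) and 46, 40 and 51 the reverse (10.0, 9.97 and 13.3), so the shared counts do not show that the clones moved together.

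The late MYCN changes were set beside those at 288 h of doxycycline, fits with no array in common. The DKK1 probe set had -0.38 at 288 h, so induction is not shown and these are changes after doxycycline. Across 11474 genes the changes correlated with r = 0.03141 (rho = 0.05593; genes are not independent replicates), and with -0.05044 over the 595 genes changed at least 2-fold in either. At least 2-fold in the fits, 2 genes were higher in both, against 1.042 if independent, 8 lower in both, against 3.111, 13 higher with MYCN and lower after doxycycline, against 1.696, and 2 the reverse, against 1.911. Ribosomal proteins had medians of 0.15 with MYCN and -0.05 after doxycycline, each of the other sign under quantile normalisation. Matrix genes had -0.43 and -0.04, and ribosome biogenesis 0.43 and 0.07. DKK1 itself had -1.04 with MYCN, and SYNPO2 -0.73 with MYCN (-1.35 in SKNAS-NmycER and -0.11 in SHEP-21N) and 1.38 after doxycycline, none of these past the threshold.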

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

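The tests of the labelling batch, of RNA degradation in both 0 h arrays and of the DKK1 probe set were chosen only after the results were seen.

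The lines differed in their MYCN response, by an interaction test whose spread comes from the arrays after 0 h, in 96 genes, but in 0 with eBayes without a trend and in 1 without any of the SKNAS-NmycER 24, 72 or 144 h arrays or the SHEP-21N 24 h array. Both cell cycle lists had the higher change in SHEP-21N (DNA replication -1.464 and mitosis -1.296, SKNAS-NmycER minus SHEP-21N). Array scaling is argued against, since 114 genes were called after quantile normalisation, and so is RNA degradation in the SHEP-21N 0 h array, whose GAPDH 3' over 5' ratio of 0.922 lay below the 0.95 to 0.997 of the other 3. The difference also rests on the SKNAS-NmycER 0 h array, which stood apart from its later arrays in controls. Its actin ratio was 1.67 against 1.92 to 1.95, and its BioB signal 103 against 145 to 148. A state of that RNA or array was not tested as a cause. At 0 h the DNA replication list was lower in SHEP-21N than in SKNAS-NmycER by a median log2 difference of -1.873, and at 24 h by -0.08769 (mitosis -1.647 and then -0.1166), so a candidate explanation is that fewer SHEP-21N cells were cycling at 0 h and that MYCN brought them to the level SKNAS-NmycER already had. This stays a hypothesis that rests on 1 array at 0 h, and the culture's density, the switch and the line were not varied apart.

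The other differences between the lines were found by the same test. For genes they were 5.25 for NPW, 5.21 for JAG2, 3.50 for CCN3, 3.23 for PER3, 2.86 for BHLHE41, -3.997 for E2F1, -3.80 for HAUS8, -3.50 for MYBL2, -3.06 for ATAD2 and -3.04 for HUWE1. For lists they were 0.2568 for ribosomal proteins (0.03 under quantile normalisation), 0.3954 for translation factors, -0.3258 for mesenchymal markers, 0.3808 for the unfolded protein response and 0.8975 for ATF4 genes. None of these lists was called with an estimated correlation, and mesenchymal markers lost their call with the mean of probe sets and without a trend as well.

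The clones differed in their response to doxycycline, by an interaction test whose spread comes from the arrays after 0 h, in 492 genes, but in 1 with eBayes without a trend, 132 with the mean of probe sets and 165 without a filter, and the later c66 arrays are the spike-in batch, so batch and clone response coincide. Array scaling is argued against by 494 genes called after quantile normalisation, and RNA degradation in the c66 0 h array, as far as it shows as a 3' excess, by a GAPDH ratio of 0.986, under the 1.0 to 1.09 of the other 7. The batch as the whole cause would open the gap between the clones after 0 h, and a share of 0.199 of the called genes had the larger gap then. The median absolute gap was 0.7595 at 0 h, where both arrays lie in 1 batch, and 0.3077 after. These values do not decide on the batch, since the 0 h gap is 1 array against 1 and the later gap spans all later times. The genes were also called for a difference between these gaps. Deviations of the 0 h arrays alone can therefore lower the share and widen the 0 h gap. For the 98 genes with the larger gap after 0 h, batch and clone cannot be told apart either, since no c66 array after 0 h lies in the other batch. The c66 0 h array also stood apart in its ribosomal RNA controls, with 1.99 for 18S against 33.4 to 151 on the other 7 and 52.2 for 28S against 417 to 880, so whether a state of that culture, of that array or a true difference of the clones made the 0 h arrays differ stays open.

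The other differences between the clones were found by the same test. For genes they were 4.42 for ACKR3, 3.77 for KRT18, 3.33 for SNAP91, 3.09 for HBQ1, 3.07 for MAP4K1, 0.96 for LRP6, -4.55 for NTN3, -4.18 for DPP9, -3.43 for RAB42, -3.39 for FAM20C and -3.35 for LIMK1. For lists they were 0.2045 for ribosomal proteins (0.08 under quantile normalisation) and 0.378 for mitosis. Neither list was called with an estimated correlation, and ribosomal proteins were not called without a trend either.

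The DKK1 probe set did not rise after doxycycline, with a highest fitted log2 change of 0.1098 at 72 h. A probe set that lies outside the transgene may stay flat while the transgene is expressed, and a transgene that was not induced gives the same value. These cannot be told apart, since the array holds 1 DKK1 probe set and transgene sequence and DKK1 protein were not analysed here.

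For the 1641 genes called between the clones, 1 of the 32 splits of the 8 arrays into 4 and 4 that could be fitted with the time block (of 35) gave as many, the real one, and the highest count of the others was 0. The splits that can be exchanged under a time block are the 8 with 1 array of each time on either side, too few for a share under 0.05. A split that mixes the clones also leaves their difference in the spread.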

How the results depend on the processing

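The spike-in batch block and the other MYCN probe set were chosen only after the signals were seen. Counts of 0 genes for both MYCN times and all DKK1 times held under every alternative but those given here, and the sign of DKK1 after MYCN activation under all. Outside the left-out arrays, named genes kept their direction and side of the threshold in 1472 values, lost a call in 65, gained a call in 12 and changed sign without a call in 30. With 1 array left out these were 867, 75, 28 and 29 values. The cause was not tested except where the construction of the alternative shows it.

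With the pseudocount at the 40th percentile, 239 and 296 genes were at least 2-fold higher and lower in SKNAS-NmycER, and 432 lower in SHEP-21N. With a pseudocount of 1, 1 list was called between the clones, and the SHEP-21N change of MYCN was 5.324 as the rule then picked another probe set (-0.213 otherwise). On the probe set with signal in SHEP-21N it was 5.103. Under quantile normalisation 3 lists were called at 24 h of doxycycline, 0 at 72 h and 288 h, 1 between the clones and 1 in the clones' difference in response. The ribosomal protein median reversed there to -0.03869 and -0.005144 after MYCN and to 0.03238 at 288 h of doxycycline. Without a filter the lists called were 3, 5 and 5 at the DKK1 times and 2 between the clones, the interactions called 165 genes between clones and 27 between lines, and 2-fold counts were 1129 and 1237 in SKNAS-NmycER and 1706 and 1937 in SHEP-21N. With the stricter filter 1 list was called at 72 h, and the 2-fold counts were 231 and 305 in SKNAS-NmycER and 217 and 365 in SHEP-21N.

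With the mean of probe sets 3 lists were called at 24 h and 5 at 72 h of doxycycline and 1 between the clones, and 1045 genes between the clones, 132 and 63 in the interactions of clones and lines, and 439 genes 2-fold lower in SHEP-21N. With every probe set these were 2536, 823 and 51 probe sets, and the 2-fold counts 838 and 1079 in SKNAS-NmycER and 1207 and 1598 in SHEP-21N. With no replicate block 8 lists were called at 24 h of MYCN and 2 at 288 h of DKK1. Without a trend in eBayes 1 list was called at 72 h, 0 at 288 h and 1 in the clones' difference in response, and 513 genes between the clones, 1 in the interaction of clones and 0 in that of lines. With 1 fit over 16 arrays 41 genes were called at 24 h and 28 at the late times of MYCN, and 2, 1 and 0 lists at the DKK1 times. With all times after 0 h pooled 21 genes were called for MYCN and 1 for DKK1, and 3 lists for DKK1, with DKK1 itself at -0.1217. With an estimated correlation camera called 0 lists in each comparison. The spike-in batch block leaves the c63 0 h array alone as the 0 h arm, and a clone term of 1 array against 1, each taken to vary like the rest. With it 33, 25 and 1 genes were called at the DKK1 times and 2 over any time, DKK1 at 24 h had 0.07415, 3 lists were called at 288 h and 2 between the clones, and the mitosis median reversed to -0.04018 at 24 h and -0.08437 at 72 h. Lists that lost a call after 24 h of MYCN were translation factors under quantile normalisation (0.3323), translation factors (0.05451), p53 targets (0.05148) and cholesterol genes (0.05496) with the mean of probe sets, translation factors, p53 targets, matrix, actin, ATF4 and cholesterol genes with no replicate block (0.0551 to 0.2363), interferon genes with 1 fit over 16 arrays (0.1049) and ATF4 genes with all times pooled (0.11). At the late times they were adrenergic (0.1656), mesenchymal (0.1526) and actin genes (0.09315) with no replicate block, actin genes with the mean of probe sets (0.05612) and adrenergic markers with all times pooled (0.05016). After doxycycline every list called lost its call under at least 1 alternative: without a trend, for example, actin genes at 24 h (0.05664), DNA replication (0.07965) and mitosis (0.09949) at 72 h and ribosomal proteins at 288 h (0.2647).

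With 1 array left out, counts of genes ranged from 0 to 161 at 24 h and 0 to 58 at the late times of MYCN. They ranged from 0 to 1088, 0 to 1097 and 0 to 1746 at the DKK1 times, 0 to 597 for any time, 438 to 2969 between the clones, 181 to 846 in the interaction of clones and 1 to 567 in that of lines. The lists called ranged from 6 to 15 at 24 h and 7 to 12 at the late times of MYCN, 2 to 5, 1 to 3 and 0 to 3 at the DKK1 times, 0 to 4 between the clones and 6 to 10 in the difference of lines. DKK1 ranged from -1.721 to -0.8639 and -1.502 to -0.5803 after MYCN, and from -0.3466 to 0.1597, -0.1585 to 0.378 and -0.5641 to -0.1987 after doxycycline. The correlation of MYCN with DKK1 changes ranged from 0.001234 to 0.04561. Medians of lists that reversed ranged at 24 h of MYCN from -0.05081 to 0.3362 for ribosomal proteins, -0.07175 to 0.3263 for translation factors and -0.8083 to 0.001461 for ATF4 genes. At the late times they ranged from 0.0315 to 0.2665 for ribosomal proteins, -0.12 to 1.554 for DNA replication, -0.1476 to 1.259 for mitosis and -0.3484 to 0.5877 for ATF4 genes. At the DKK1 times they ranged from -0.04018 to 0.304 and -0.08437 to 0.2785 for mitosis at 24 and 72 h, and from -0.1521 to 0.07014 for ribosomal proteins at 288 h. A fit that leaves out a 0 h array rests mainly on the other line or clone, whose lone array is taken to vary like the rest.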

Other observations

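The genes in this part were chosen after their values were seen, and so were the tests of them; the values have no p-value, since each line has 1 array per time. In SHEP-21N the pregnancy-specific glycoprotein genes, secreted relatives of the CEA adhesion proteins, were lower as a family: the median of 6 was -0.69, -2.05 and -1.96 at 8, 24 and 120 h, with 2, 5 and 4 at least 2-fold lower. Their probe sets share sequence, so they are not 6 independent readings. Of 13 tubulin genes 7, 6 and 0 were at least 2-fold higher (medians 1.11, 0.82 and 0.26). Of 9 genes for chemokines and IL6, 5 were at least 2-fold lower and 0 higher at 8 h (median -1.19), 1 lower and 1 higher at 24 h, and 6 higher and 0 lower at 120 h (median 1.26). CXCL8, which attracts neutrophils, had signals of 297 at 0 h, 205.5, 400.6 and 1656, and CXCL2 358, 132.5, 525.5 and 1094.

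Of the clock genes, PER3 and BHLHE41 were called as differing between the lines, and others went both ways. In SKNAS-NmycER 6 of 16 were at least 2-fold higher and 2 lower at 144 h, with PER2, a repressor of the clock, at 43.1 and 239 and BHLHE41 at 44.7 and 244, and NPAS2, an activator, at 120 and 45.5, lower as in SHEP-21N with 76.8 and 33.4. In SHEP-21N 0 of 14 were 2-fold higher at any time and 6, 5 and 4 were lower, with PER3 at 201, 44.0, 55.2 and 65.2 and DBP, a clock output factor, at 245, 24.4, 62.7 and 107. Of 15 Notch pathway genes in SKNAS-NmycER 4, 5 and 4 were at least 2-fold higher at 24, 72 and 144 h, among them JAG2, HES6 and NRARP, while the family median was 0.33, 0.05 and -0.02, the last of which became 0.05 under quantile normalisation. At 144 h 1 was at least 2-fold lower, and NRARP started at 2.20, under the pseudocount. In SHEP-21N 1, 1 and 0 of 14 were at least 2-fold higher and 2, 2 and 4 lower, with JAG2 at 59.7 and 27.6.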
